A study of Homo sapiens with 10 samples.

How the data were processed

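RNA from 10 samples of SKBR3 cells was compared on 1-colour Affymetrix oligonucleotide arrays, on which biotin-labelled cRNA hybridises to sets of short probes. Per the labels' protocols, the cells were grown with charcoal-stripped serum, transfected with siRNA against p53 (p53i) or against the bacterial LacZ gene (LacZi, the negative control), and left untreated or given calcitriol (the hormonal form of vitamin D3, D3 here) at 100 nM for 8, 20 or 50 h. Total RNA was extracted with Trizol and 6 ug were labelled, per the labels. The series text puts D3 48 h after transfection and the sample text 24 h, and both are given here because nothing in the sources used settles it.

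The deposited table gave 1 intensity for each of 54675 probe sets on each of 10 arrays, on a linear scale. Per the submitters' processing notes these are MAS5 signals. The version is not given in the sources used here. The mean of each array's values, without the lowest and highest 2%, was 200 on every array, so the deposited intensities had been scaled array by array, and no further normalization between arrays was applied. Low MAS5 signals lie near the background and are noisy, so fold changes of weakly expressed genes are uncertain. Detection calls were not used here.

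Each sample was placed in its group from its own labels. There were 8 groups, with 2 arrays in each untreated group and 1 array per siRNA at each of 3 D3 times. The title of the p53i 8 h sample spells the siRNA differently from the others, and its group was taken from its other labels. The untreated arrays are labelled as biological replicates. For the D3 arrays nothing states separate cultures, and p-values measure only the spread between these samples. The array numbers in the labels run through the LacZi arrays first. The order in which arrays were processed is not given in the sources used here, so it was not tested as a batch. No untreated array is labelled as harvested with the D3 times, so D3 and time in culture cannot be told apart either.

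Probe sets were named through the platform annotation given for the series. Of the probe sets, 41091 carried 1 gene symbol, 1801 several and 11783 none, and none was named from a probe set with several. Symbols were checked by gene ID against RefSeq, which changed 0 of them. Another 54 symbols were kept as annotated. The target of the p53 siRNA had no row in the gene table used and was not analysed here, so the knockdown was not checked by its target.

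Signals were converted to log2(signal + 16), and fold changes are on that scale, which understates changes of weakly expressed genes. Each gene was represented by the probe set with the highest mean. Probe sets in the upper 50% by mean log2 signal were kept, corresponding to a signal above 35.3, which left 12034 genes. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Knockdown in untreated cells came from a model with 8 group means and 2 residual degrees of freedom. Knockdown over all conditions and the D3 effects came from an additive model of siRNA and D3 time with 5 residual degrees of freedom. D3 effects within each siRNA and their difference (the interaction) came from the same model with a siRNA-by-D3 term and 4 residual degrees of freedom. At each D3 time a lone array per siRNA is assumed to vary like the others. The difference between 50 and 8 h was added after the counts at the D3 times were seen.

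Gene groups were tested with camera on 21 lists fixed before the data were examined, at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists. Another 6 lists of markers of other cells served as a check for contamination. The genes named were also fixed by rule: for knockdown over all conditions, D3 (mean of the 3 times) and the interaction, the 10 largest rises and the 10 largest falls among genes past the threshold that moved the same way in every matched comparison, the 5 with the smallest p as values only where fewer than 5 passed, the siRNA's target, VDR, CYP24A1, CDKN1A, MDM2 and ERBB2 always, and up to 4 members of each list. Genes outside this rule are named as chosen after their values were seen.

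Alternatives covered quantile normalization, median centring, no offset and an offset of 64, no filter and the upper 25% of probe sets, single probe sets and probe-set means, no intensity trend, group means, the replicate number as a block, and each array left out. The ratio of the 3' to the 5' control probe sets of ACTB, a measure of RNA integrity and labelling, was added afterwards as a covariate, as was a fit without the arrays with the highest ratio. The test was checked on simulated data built on the measured spread of 12034 genes. With a log2 change of 1 it recovered 90% of 100 changed genes for knockdown over all conditions, 88% for D3, and 31% for the interaction. At a log2 change of 2 the interaction recovered 76%. In simulated data without any changed gene it made 0 calls. In the data with changed genes it also called some unchanged ones: 8 for knockdown over all conditions, 9 for D3 and 6 for the interaction. Data were prepared in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9. The number of arrays limits the precision.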

Results

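Transcript levels were measured in SKBR3 cells, an established HER2-amplified breast carcinoma line that carries mutant p53, on 10 Affymetrix arrays. Cells received siRNA against p53 (p53i) or LacZ (LacZi, negative control), and each siRNA was represented by 5 arrays. Of these, 2 were untreated and 1 each was taken after 8, 20 and 50 h with 100 nM calcitriol (D3). The comparisons ask how siRNA against mutant p53 changes expression, how D3 changes it, and whether the response to D3 differs between the siRNAs. Median signals were 35.7 to 44.3 per array. Between the untreated duplicates, 321 of 12034 genes (2.67%) differed at least 2-fold in LacZi cells and 431 (3.58%) in p53i cells. The 6 lists of markers of other cells had median signals of 19.3 to 59.8. For knockdown over all conditions and for D3 over the 3 times, the members called were TFF3, higher by 0.68 in p53i cells and lower by 0.85 with D3, and KRT5, higher with D3. At 50 h with D3, FGB, a fibrinogen chain and liver marker, was also called, higher by 2.74 (limma adjusted p = 0.00568), with signals of 221 and 272 on the 50 h arrays and 4.33 to 70.6 on the others, and it lay below the signal filter without either 50 h array. TFF3 and FGB were chosen after their values were seen. The target of the p53 siRNA was not analysed here, so no direct measure of the knockdown is given.

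In p53i cells, the strongest rises were of interferon-stimulated genes. IFI27, an interferon-induced mitochondrial protein, rose by 4.30 ± 0.28 (SE) on the log2 scale, from a mean signal of 34.7 ± 24.8 (SD, n = 5) to 1030 ± 579 (SD, n = 5). IFIT1, which binds foreign RNA, rose by 3.56 ± 0.34, the ubiquitin-like ISG15 by 2.71 ± 0.19, and XAF1, a XIAP-associated factor, by 2.55 ± 0.31. The restriction factor BST2 rose by 2.02, the oligoadenylate synthetases OAS1 and OAS3 by 2.01 and 1.75, the antiviral GTPase MX1 by 1.96 and IFI6 by 1.76. CCDC24 rose by 1.76. All of these were higher in 4 of 4 comparisons matched on D3 time, which the rule for naming them required. Their limma adjusted p was 2.67e-05 to 0.00462. For XAF1 the difference was -0.06 without an offset and 0.11 without p53i untreated replicate 1, neither called, as another of its probe sets then had the highest mean (the reported one stood at 2.58 without that array), and without p53i untreated replicate 2, p53i 20 h or p53i 50 h XAF1 lay below the signal filter. Without the 2 arrays with the highest ACTB 3'/5' ratio CCDC24 was not called (1.37), and XAF1 lay below the signal filter. The sizes of weakly expressed genes moved with the offset: IFI27, whose mean LacZi signal was below the median of a typical array, stood at 5.15 with no offset and 3.29 with an offset of 64, IFIT1, with LacZi signals of 1.00 to 29.9, at 5.73 and 2.20, and with 64 XAF1 stood at 1.37, MX1 at 1.24 and CCDC24 at 1.05, all called.

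Of the 31 measured interferon-stimulated genes, 21 rose and 0 fell in p53i cells over all conditions, and 25 rose adjusted over the list alone. Their median log2 difference was 0.998 (camera adjusted p = 1.3e-24, and adjusted p = 0.0859 with an estimated correlation). Matched medians were 0.94 in untreated cells, 0.78 at 8 h, 0.97 at 20 h and 1.55 at 50 h. The transcription factor subunit IRF9 rose by 1.60. With the ACTB ratio as a covariate the list's median was 0.957 and 11 members were called. The ACTB 3'/5' ratio was 6.22 ± 1.77 (SD, n = 5) on the p53i arrays and 4.46 ± 0.523 (SD, n = 5) on the LacZi arrays (exact permutation test, two-sided, p = 0.0714).

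**Figure D1:**
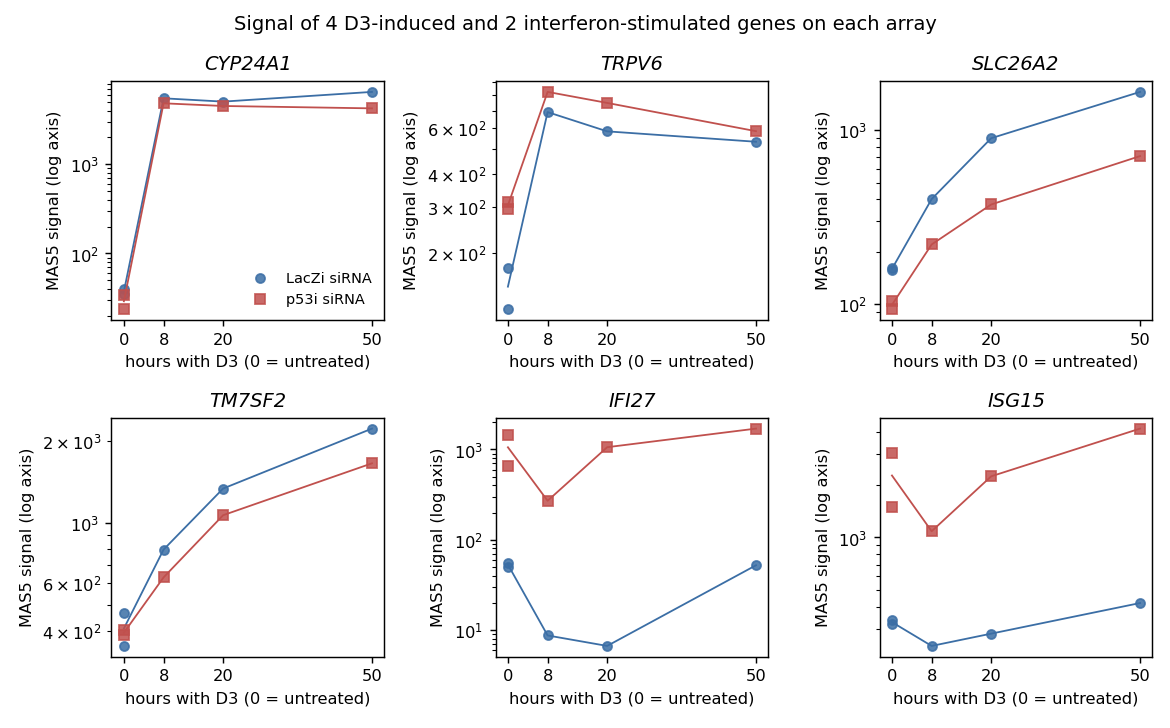
MAS5 signal (log axis) of 4 D3-induced and 2 interferon-stimulated genes against hours with D3. Each point is 1 array, 0 h is untreated, and lines join the mean of the untreated pair to the arrays at later times. CYP24A1 had a mean of 33.3 on the untreated arrays and lay at 4234 to 6476 on the D3 arrays. IFI27 was higher on the p53i array or arrays at each time.

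Genes that fell in p53i cells were led by ANXA1, a phospholipid-binding annexin, by 1.59 ± 0.21 on the log2 scale, from 422 ± 126 to 130 ± 46.8 signal units (SD, n = 5 each). The immediate early factor EGR3 fell by 1.26, the calcium-binding S100A7 by 1.25, the mitochondrial carrier SLC25A24 by 1.22, KCTD12 by 1.18, RAMP3 by 1.13, the fatty-acid-binding FABP5 by 1.08 and CLCA2 by 1.05. NAA50, an N-terminal acetyltransferase, fell by 1.17 ± 0.10, and both of its other probe sets moved the same way. LOC101928343 fell by 1.21, but the difference was 0.20 without the arrays with the highest ACTB ratio, where another probe set had the highest mean. Adjusted p for these genes was 0.000119 to 0.048 (limma), and each was lower in 4 of 4 matched comparisons, as the naming rule required. Several of these calls were lost with 1 array left out: KCTD12 without LacZi untreated replicate 1 (-1.16) or any 20 h (-1.10) or 50 h array (-1.07), CLCA2 without any D3 array (-1.13 to -0.93, and -0.74 without p53i 20 h), LOC101928343 without LacZi 8 h (-1.11) or any 20 h (-1.20) or 50 h array (-1.10), and RAMP3 without p53i untreated replicate 1 (-0.87), p53i 8 h (-1.23) or p53i 50 h (-1.01), with RAMP3 below the signal filter without any of the others. The values of CLCA2 without p53i 20 h and LOC101928343 without LacZi 8 h came from another probe set, which then had the highest mean, and the reported ones stood at -1.13 and -1.37. Without the 2 arrays with the highest ACTB ratio EGR3 (-1.11), KCTD12 (-0.93) and CLCA2 (-1.19) were not called, and RAMP3 lay below the signal filter. With an offset of 64, EGR3 stood at -0.83, LOC101928343 at -0.66, KCTD12 at -0.64, CLCA2 at -0.63 and RAMP3 at -0.56, all called.

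Over all conditions, 781 genes were called between the siRNAs, 407 higher and 374 lower in p53i cells, of which 28 and 15 changed at least 2-fold. The camera test also called 4 lists besides the interferon-stimulated genes, none of which was called with an estimated correlation. In the mevalonate and cholesterol synthesis list 2 of 18 members rose, MSMO1 by 0.61 and MVK by 0.50 (adjusted p = 0.00315, and adjusted p = 0.715 with an estimated correlation), and 5 rose adjusted over the list alone. Luminal epithelial genes included 5 of 28 that rose, among them KRT8 by 0.42 and CLDN3 by 0.39 (adjusted p = 0.00427, and 0.606 with an estimated correlation), and 10 rose adjusted over the list alone. In the G2/M list 3 of 36 fell, CDK1 by 0.38, CKS1B by 0.36 and KIF11 by 0.49 (adjusted p = 0.00427, and 0.733 with an estimated correlation), and 4 fell adjusted over the list alone. In the HER2 amplicon list PGAP3, ORMDL3 and GRB7 rose by 0.55, 0.61 and 0.38 and PNMT fell by 0.67 among 15 measured (adjusted p = 0.0462, and 0.606 with an estimated correlation), and the same numbers passed adjusted over the list alone. With the ACTB ratio as a covariate the lists' adjusted p was 0.594 for G2/M, 0.102 for luminal and 0.28 for mevalonate. The G2/M call was lost without p53i untreated replicate 2 (adjusted p = 0.0751), and the HER2 call without p53i untreated replicate 1 (0.0776), LacZi 50 h (0.131) or p53i 50 h (0.13). The luminal members XBP1 and KRT7 had differences of -0.02 and -0.01 when probe sets were averaged. Leaving out each of the 10 arrays in turn ended the call of MSMO1 in 2 fits (without either 20 h array), of XBP1 in 4 (without any 20 or 50 h array), of CLDN3 and GRB7 in 6 each, of CDK1 and KRT7 in 7 each, of MVK, CKS1B and KIF11 in 8 each and of PNMT in 9, with the sign kept in all of them, and that of KRT8, PGAP3 and ORMDL3 in 0.

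Lists without a call between the siRNAs had adjusted p of 0.139 to 0.979. Among p53 targets 2 of 30 rose, CYFIP2 by 1.29 and PLXNB2 by 0.34. CDKN1A, the cyclin-dependent kinase inhibitor, had a difference of -0.49 and MDM2, the p53 ubiquitin ligase, of -0.08, and neither was called. Of 18 genes reported to depend on mutant p53, CCNG2 rose by 0.52 and MCM6, MYC and CDK1 fell by 0.56, 0.53 and 0.38. With each array left out in turn, the call was lost in 3 of 10 fits for CCNG2 (without LacZi untreated replicate 2 or any 50 h array), 6 for PLXNB2 and 7 each for MYC and CDK1, and in 0 for CYFIP2 and MCM6. The VDR difference was -0.22 and that of ERBB2 was 0.17, and neither was called.

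The count of 781 was lower with several arrays left out: 168 without the p53i 20 h array, 177 without LacZi 20 h, 259 without either 50 h array, 387 and 400 without LacZi untreated replicates 2 and 1, 402 without LacZi 8 h and 410 without p53i 8 h. It was 94 with the ACTB covariate, 109 without the arrays with the highest ratio and 51 with group means. In untreated cells alone, with 2 arrays per siRNA, only IFI27 was called, 3.86 ± 0.34 (SE) higher in p53i cells on the log2 scale, while 1377 genes had an unadjusted p under 0.05 where 602 would by chance. The number of genes called, 1 with all arrays, was 269 without p53i untreated replicate 1, 36 without LacZi untreated replicate 1, 9 without LacZi untreated replicate 2 and 3 without p53i untreated replicate 2.

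With D3, CYP24A1, the enzyme that inactivates calcitriol, rose by 6.69 ± 0.10 (SE) on the log2 scale. The mean signal was 33.3 ± 6.86 (SD, n = 4) on untreated arrays, below the median of a typical array, and 5094 ± 804 (SD, n = 6) on D3 arrays. The untreated signals were not shown to lie above background, so the offset sets part of the size, which was 7.27 with none and 5.72 with an offset of 64. The sulfate transporter SLC26A2 rose by 2.06 ± 0.13, the retroviral envelope gene ERVW-1 by 1.81, the protease KLK6 by 1.76, PNMT of adrenaline synthesis by 1.64 and the basal keratin KRT5 by 1.59. The calcium channels ITPR1 and TRPV6 rose by 1.58 and 1.55, the Wnt carrier WLS by 1.53 and the sterol reductase TM7SF2 by 1.52. Falls were led by CLTCL1 by 1.28, the DNA damage binding gene DDB2 by 1.19 and the collagen COL5A2 by 1.19, followed by RFTN1 by 1.06. TOX3, FREM2, CNP, FBXO32, PCP4 and GPRC5B fell by 0.90 to 0.95. All moved the same way on 6 of 6 D3 arrays, which the naming rule required, with limma adjusted p of 7.91e-13 to 0.0405. SLC26A2 rose by 1.24 without LacZi 20 h and 1.22 without LacZi 50 h, where another of its probe sets had the highest mean and the reported one stood at 1.99 and 2.00, and KRT5 lay below the signal filter without LacZi 20 h or any 50 h array. Calls were lost without LacZi untreated replicate 1 for DDB2 (-1.04), GPRC5B (-0.82), FBXO32 (-0.84) and CNP (-0.75), without p53i 20 h for FBXO32 (-0.87), without LacZi 20 h (-0.85), p53i untreated replicate 1 (-0.81), p53i 8 h (-0.87) or p53i 50 h (-0.90) for CNP, and without any 1 array other than p53i untreated replicate 2 for TOX3 (-1.08 to -0.70). TOX3 was also not called without the 2 arrays with the highest ACTB ratio (-1.08). With an offset of 64, KLK6 stood at 1.09, PNMT at 1.04, KRT5 at 0.79, CLTCL1 at -0.84, DDB2 at -0.78 and TOX3 at -0.63, all called.

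Of 25 measured vitamin D receptor targets, 9 rose with D3 and 0 fell, including CYP24A1, TRPV6, KLK6 and EFL1 by 0.82, and 14 rose and 1 fell adjusted over the list alone. The median log2 difference was 0.416 (camera adjusted p = 1.92e-11, and adjusted p = 0.0117 with an estimated correlation). For D3 over the 3 times it was the only list called with an estimated correlation, and that p was 0.0585 without p53i untreated replicate 2 and 0.18 without the arrays with the highest ACTB ratio. VDR itself had a difference of -0.32, which was not called. In the G2/M list 15 of 36 fell, among them CKS1B by 0.63 and DLGAP5 by 0.71, and the median was -0.379 (adjusted p = 7.48e-22, and adjusted p = 0.158 with an estimated correlation). Adjusted over the list alone, 32 fell. In the G1/S list 13 of 34 fell, including CDC45 by 0.64 and TYMS by 0.46, with a median of -0.323 (adjusted p = 2.84e-14, and adjusted p = 0.0687 with an estimated correlation), and 23 fell adjusted over the list alone. The TYMS call was lost without LacZi untreated replicate 1, where the difference was still below 0.

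Another 3 lists were called after D3 at the preset correlation only. Of the genes reported to depend on mutant p53, ETS2 rose by 1.09 while CCNB2, CCNA2 and CDK1 fell by 0.48, 0.54 and 0.39 among 18 measured (camera adjusted p = 0.012, and adjusted p = 0.158 with an estimated correlation). Adjusted over the list alone, 1 rose and 8 fell. CCNB2, CCNA2 and CDK1 are also on the G2/M list, so this call is not separate from the fall of that list. In the calcium and ion transport list TRPV6 and ITPR1 rose among 22 (camera adjusted p = 0.0113, and adjusted p = 0.158 with an estimated correlation), and 4 rose adjusted over the list alone. TRPV6 is also on the list of vitamin D receptor targets. In the HER2 amplicon list PNMT rose and ORMDL3 fell by 0.42 among 15 (adjusted p = 0.0174, and adjusted p = 0.229 with an estimated correlation), and 3 rose and 1 fell adjusted over the list alone. The calcium call was lost without LacZi untreated replicate 2 (adjusted p = 0.0691), and the HER2 call without LacZi 8 h (0.0573) or p53i 50 h (0.0531). Of the members named, CCNB2 lost its call without LacZi 8 h or p53i 20 h, CCNA2 in 6 of 10 fits with 1 array left out, CDK1 in 7 and ORMDL3 in 9 (all but that without LacZi untreated replicate 2), with the sign kept. The remaining 15 lists had adjusted p of 0.0866 to 0.825. CDKN1A, MDM2 and ERBB2 had differences of 0.56, 0.04 and 0.06, and none was called.

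Over the 3 times, D3 gave 529 called genes, 239 higher and 290 lower, of which 43 and 4 changed at least 2-fold. The count was 124 without LacZi untreated replicate 1, 140 without p53i 20 h, 153 without LacZi 20 h, 157 without LacZi 8 h, 184 without p53i 50 h, 196 without p53i 8 h, 261 without LacZi 50 h, 268 without p53i untreated replicate 1 and 848 without p53i untreated replicate 2. D3 and time in culture were not separated by the design.

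The number of called genes was 21 at 8 h, 71 at 20 h and 518 at 50 h. CYP24A1 was up by 6.72, 6.61 and 6.75 at these times, with a 50 minus 8 h difference of 0.03 ± 0.16 (SE). SLC26A2 was up by 1.15, 2.08 and 2.96, and TM7SF2 by 0.80, 1.54 and 2.21. The difference between 50 and 8 h was 1.82 ± 0.19 for SLC26A2 and 1.41 ± 0.16 for TM7SF2 (limma adjusted p = 0.0066 for each), and 16 genes were called for it, 13 higher and 3 lower at 50 h. The G2/M list had 27 of 36 members lower at 50 h, with a median of -0.609 (camera adjusted p = 1.74e-26, and adjusted p = 0.13 with an estimated correlation). Its matched medians were -0.14, -0.41 and -0.58 in LacZi cells and -0.16, -0.38 and -0.69 in p53i cells. Between 50 and 8 h the list's median difference was -0.415 (adjusted p = 1.05e-23, and adjusted p = 0.118 with an estimated correlation). Adjusted over all genes 0 members were called for it, and adjusted over the list alone 30 of 36 were lower. At 20 h, 3 of 34 G1/S genes were lower, and 24 adjusted over the list alone, with a median of -0.440 (adjusted p = 3.44e-17, and adjusted p = 0.0458 with an estimated correlation). With 1 array left out the latter was 0.035 without LacZi untreated replicate 1 and 0.0719 to 0.166 without any other, and it was 0.198 without the arrays with the highest ACTB ratio.

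Each time rested on 1 array per siRNA. The count at 50 h was 43 without the p53i 50 h array, 85 without LacZi 50 h, 225 without LacZi untreated replicate 1, 307 without p53i 20 h, 312 without LacZi 20 h, 340 without LacZi 8 h, 344 without p53i 8 h and 929 without p53i untreated replicate 2. The count at 20 h was 5 without LacZi 20 h and 6 without p53i 20 h, and that at 8 h was 1 without LacZi 8 h and 7 without p53i 8 h. The count for 50 minus 8 h was 0 without LacZi 8 h or either 50 h array.

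**Figure D2:**
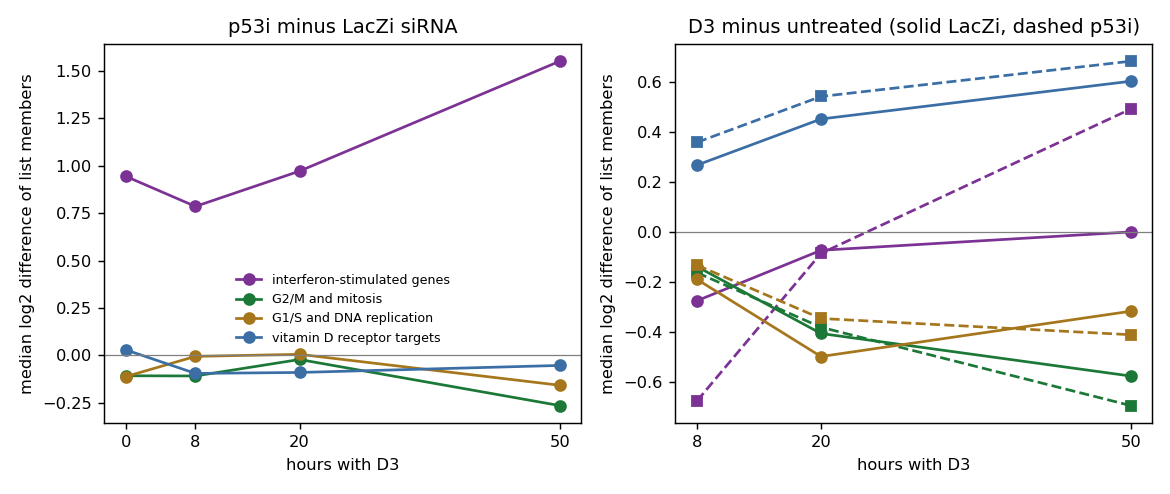
Median log2 difference of the members of 4 gene lists, on the left p53i minus LacZi at each D3 time and on the right D3 minus untreated in LacZi (solid lines) and p53i cells (dashed lines). The interferon-stimulated genes were at 0.94 in untreated cells and 1.55 at 50 h on the left, and the G2/M list reached -0.58 and -0.69 at 50 h on the right.

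The question of whether the D3 response differs with siRNA against mutant p53 was tested by the interaction. CYP24A1 rose by 6.73 ± 0.15 (SE) in LacZi cells and by 6.66 ± 0.15 in p53i cells, a difference of -0.07 with a 95% interval of -0.53 to 0.39. That difference rests on untreated signals near the background and was 0.07 with no offset and -0.19 with an offset of 64, neither called. TRPV6 rose by 1.92 and 1.19 and ITPR1 by 2.03 and 1.13, and the 95% intervals of their differences, -1.23 to -0.24 and -1.48 to -0.34, lay below 0 before adjustment (limma adjusted p = 0.893 for each). TRPV6 was at 149 signal units in untreated LacZi cells and at 304 in untreated p53i cells, and ITPR1 at 67.1 and 156. On the D3 arrays the LacZi and p53i means were 602.2 and 719.5 for TRPV6 and 323.5 and 358 for ITPR1. CDKN1A had an interaction of -0.48 and VDR of -0.35, neither called.

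Across all genes, 0 were called for the interaction by limma, with a smallest adjusted p of 0.751, and 645 had an unadjusted p under 0.05 where 602 would by chance. The smallest p values with a positive interaction were for IL17C (2.26), MAP3K12 (1.28), HACD3 (0.70), TPR (0.79) and DHX36 (0.74). Those with a negative interaction were for YWHAZ (-0.69), MAMDC4 (-2.17), GTPBP3 (-0.78), NUTM1 (-1.87) and GPANK1 (-0.99). None of them was called. Other probe sets of MAP3K12, DHX36, YWHAZ and GPANK1 had an interaction of the opposite sign. The genes with a positive interaction had lower mean signals with D3 in LacZi cells and higher ones in p53i cells. IL17C, for example, went from 105 to 49.5 in LacZi cells and from 35.7 to 109 in p53i cells. Mean signals of YWHAZ, MAMDC4, GTPBP3 and GPANK1 rose with D3 in LacZi cells and fell in p53i cells, and those of NUTM1 rose in both. None of the 21 lists was called, and the smallest adjusted p was 0.412. Without p53i untreated replicate 2 the G2/M list was called, with a median of -0.21 (adjusted p = 0.000505, and adjusted p = 0.655 with an estimated correlation). The median 95% interval extended 0.556 log2 units to either side over all genes and 0.455 over the genes called after D3. Without p53i untreated replicate 1 the interaction called 62 genes, and 0 without any other array.

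Within LacZi cells D3 gave 47 called genes and within p53i cells 65. Of those higher, 41 and 47, 21 were shared where 0.16 would be by independent lists, and of those lower, 6 and 18, 6 were shared where 0.00897 would be. Both lists came from the same fit with 1 variance per gene, which favours overlap, so they were not independent. The log2 responses of the 2 siRNAs correlated with r = 0.378 across 12034 genes, which are not independent replicates. The genes called higher with D3 over both siRNAs had median responses of 0.599 in LacZi and 0.589 in p53i cells (camera p = 0.511 for the interaction, and p = 0.535 with an estimated correlation). Those called lower had medians of -0.422 and -0.499 (p = 0.142, and p = 0.664 with an estimated correlation). These genes were picked on the same arrays, which favours a shared sign.

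**Figure D3:**
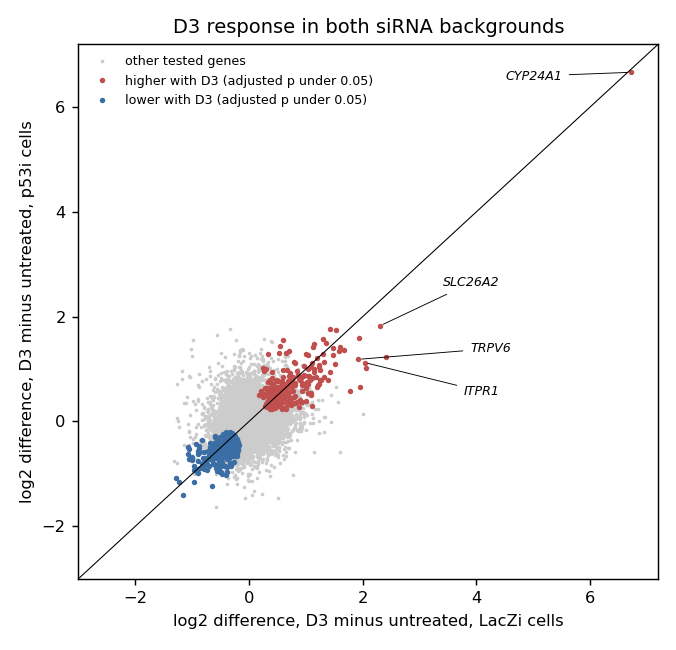
Log2 difference, D3 minus untreated, in LacZi cells (horizontal) and p53i cells (vertical) for 12034 genes; the line marks equal responses. Coloured points are the 239 genes called higher and 290 called lower over both siRNAs, and CYP24A1 lies at 6.73 and 6.66.

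The counts within each siRNA moved with single arrays. For LacZi cells 10 to 27 genes were called without any 1 of LacZi untreated replicates 1 (23) and 2 (22), LacZi 8 h (12), 20 h (15) and 50 h (10), or p53i 8 h (27), 20 h (25) and 50 h (21), and 160 and 156 without p53i untreated replicates 1 and 2. For p53i cells the counts were 28, 27, 14, 13, 6, 9, 1 and 1 in the same order, and 302 and 158 without the p53i untreated replicates.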

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

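The fits with the ACTB ratio and the splits within D3 times were chosen after the data were seen. The control probe sets of ACTB lie outside the comparisons. Their 3'/5' ratio had a mean of 6.22 on the 5 p53i arrays and 4.46 on the 5 LacZi arrays, a difference in data that no comparison used. It was highest on p53i untreated replicate 2 (8.72) and the p53i 20 h array (7.11), and the exact permutation p was 0.0714.

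RNA quality or labelling of the p53i arrays could add to the genes called between the siRNAs. With the ratio as a covariate the called genes kept 84.3% of their size (median 0.461 without and 0.388 with it) and all 781 kept their sign. The genes were picked on the same arrays without the covariate, which favours a kept sign and size. The values thus argue only weakly against quality as the whole cause. Only 82 of them stayed called, as the median SE went from 0.101 to 0.117 and the differences shrank, so that quality as a part of the cause stays open. Of 100 splits of the arrays into 5 and 5, only 1, the real one, gave as many genes (781 against a highest other of 320). In 24 splits that part each D3 pair it was again 1 (highest other 0), the fewest that such a test can give. The count was thus not matched by any other split tried. Chance differences between transfections or cultures are not excluded, since splits of the arrays cannot separate them from the siRNA.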

How the results depend on the processing

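The RNA-quality settings, the 50 minus 8 h comparison and the values of reported probe sets were chosen after seeing the data. All values are numbers of genes or lists called, and the cause of a change was not tested unless the setting itself fixes it, as with fewer genes, arrays or degrees of freedom. Quantile normalization, median centring and an offset of 64 left every count within 1.5 times of its reported value, as did no offset except for 50 minus 8 h (5). With no filter on signal, calls were 0 for knockdown in untreated cells, 473 for knockdown over all conditions, 345 for D3, 41 at 20 h, 327 at 50 h, 28 in LacZi cells, 15 in p53i cells and 4 for 50 minus 8 h. The upper 25% of probe sets gave 9 for 50 minus 8 h, and single probe sets gave 7 for it and 2 for knockdown in untreated cells. Means of a gene's probe sets gave 0, 381, 319, 13 at 8 h, 45 at 20 h, 336 at 50 h, 21 in LacZi cells, 8 in p53i cells and 5 for 50 minus 8 h, in the order above. Without the intensity trend the counts were 0, 164, 88, 5, 16, 107, 11, 2 and 2. With 8 group means, knockdown over all conditions gave 51, D3 52, its times 4, 9 and 54, LacZi cells 11, p53i cells 3 and 50 minus 8 h 0. With the ACTB ratio as a covariate, knockdown gave 4 in untreated cells and 94 over all conditions, 20 h gave 114 and p53i cells 262. Without the 2 arrays with the highest ratio these were 3, 109, 7 and 8, and LacZi cells gave 73. Leaving out each array in turn gave 1 to 269 for knockdown in untreated cells, 168 to 1035 over all conditions, 124 to 848 for D3, 1 to 28 at 8 h, 5 to 193 at 20 h, 43 to 929 at 50 h, 10 to 160 in LacZi cells, 1 to 302 in p53i cells, 0 to 62 for the interaction and 0 to 25 for 50 minus 8 h. At 8 h the counts were 12, 11, 12, 13 and 12 without LacZi untreated replicates 1 and 2, LacZi 50 h, p53i 20 h and p53i 50 h, and at 20 h 25, 43, 44, 193 and 41 without LacZi untreated replicate 1, LacZi 8 h, LacZi 50 h, p53i untreated replicate 2 and p53i 8 h. For 50 minus 8 h they were 9, 8, 3, 25, 1 and 3 without LacZi untreated replicates 1 and 2, LacZi 20 h, p53i untreated replicate 1, p53i 8 h and p53i 20 h. The interaction called 0 genes in every other setting run. Its lists, 0 called in the reported fit, included calls at the preset correlation without single arrays: hypoxia and glycolysis without LacZi untreated replicate 2 (adjusted p = 0.0157), LacZi 20 h (0.00526) or p53i 20 h (0.0052), interferon-stimulated genes without LacZi 8 h (0.00888) or p53i 8 h (0.0106), and G2/M (0.000505), mevalonate (0.00519) and stress response (0.0231) without p53i untreated replicate 2. Without the 2 arrays with the highest ACTB ratio G2/M (0.000123), mevalonate (0.0286) and hypoxia (0.0238) were called. None of these was called with an estimated correlation. An estimated correlation left 0 of 5 lists for knockdown and 1 of 6 for D3. Of 3174 values of named genes under an alternative, 2407 kept side and direction, 752 lost the call, 9 gained it and 6 reversed. These were XAF1 for knockdown with no offset (-0.0612), LRP5 (-0.0221), XBP1 (-0.0246) and KRT7 (-0.00893) for knockdown with probe-set means, LOC101928343 for knockdown without the arrays with the highest ACTB ratio (0.20), and POLH for D3 without the LacZi 20 h array (0.0166; -0.875 without the p53i 50 h array). For XAF1, LOC101928343 and POLH another probe set then had the highest mean, and that of POLH reported here stood at -0.84. Signals near the background, where log2 of the signal is noisy, limit weakly expressed genes, and all fits with a group reduced to 1 array assume that it varies like the others.

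With the replicate number as a block (the replicate block), 659 genes were called for knockdown in the 4 untreated arrays and 1302 over all conditions. The numbers are shared by only 2 pairs, nothing in the labels ties them to a batch, and same-numbered untreated arrays deviated with r = 0.215 across genes. The labels number only the untreated arrays. Over all conditions the block was a term for the untreated replicates 2, with the D3 arrays on the same level as the untreated replicates 1. D3 effects were not read from this fit. They would rest on a number that no D3 label gives and set D3 against the untreated replicates 1 alone. The interaction stayed at 0.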

Other observations

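Among the tests below, the fits with the ACTB ratio and those on siRNA molecules, time in culture, dependence on mutant p53 and the splits within D3 times were chosen after the result was seen. Other gene groups held members that moved in both comparisons. Over all genes, 28 were called higher in both where 8.08 would be by independent lists. Another 21 were called lower in both where 9.01 would be. Both comparisons came from the same fit with 1 variance per gene, which favours overlap. Genes called in opposite directions were not counted, so the members named here do not show that the comparisons oppose each other. CYFIP2, a p53 target, rose by 1.29 in p53i cells and fell by 0.73 with D3, and DDB2 and POLH, a polymerase that copies past DNA damage, fell with D3 by 1.19 and 0.79, so that 3 of 30 measured p53 targets fell and 0 rose (camera adjusted p = 0.755). The POLH call was lost in 7 of 10 fits with 1 array left out. In 4 of these another probe set had the highest mean, with a difference of 0.0166 without the LacZi 20 h array, where the reported probe set stood at -0.84. In the other 3 the reported one was kept, at -0.79, -0.74 and -0.73. THBD, the thrombin receptor, fell by 1.01 with the p53 siRNA and rose by 1.02 with D3, BCL2L11, a pro-apoptotic BCL2 relative, fell by 0.40 and rose by 0.42, and the urokinase receptor PLAUR fell by 0.83 and rose by 0.43. The hyaluronan receptor CD44 fell by 0.92 in p53i cells and TAGLN, an actin-binding gene, rose by 0.81. Of the lipid synthesis genes, DGAT2 and ELOVL6 fell by 0.75 and 0.51 in p53i cells. The D3 value of THBD was chosen after it was seen. With each of the 10 arrays left out in turn, the knockdown call was lost in 1 fit for THBD (without LacZi 50 h), 2 for ELOVL6, 3 for DGAT2, 6 for BCL2L11, 8 for CD44 and 10 for TAGLN, and the D3 call in 1 for CYFIP2 and DDB2 (without LacZi untreated replicate 1), 6 for BCL2L11 and 9 for PLAUR.

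With D3, the oxidative stress list had 3 of 28 members higher, the exporter ABCC3 by 0.83, TXNRD1 by 0.46 and AKR1B10 by 0.96, and TXNIP lower by 0.87 (adjusted p = 0.216 over the 3 times). At 50 h alone 3 were higher and 2 lower, and camera called the list higher (adjusted p = 0.018, and adjusted p = 0.173 with an estimated correlation). That call was lost without the p53i 50 h array. For 50 minus 8 h camera called the list higher, with a median of 0.177 (adjusted p = 0.000113, and adjusted p = 0.118 with an estimated correlation). There 24 of 28 members had positive differences. Over all genes 0 were called higher and 1 lower, and adjusted over the list alone 2 higher and 1 lower. Of the 21 lists, 7 were called at 8 h, 7 at 20 h, 10 at 50 h and 9 for 50 minus 8 h at the preset correlation, and 1, 2, 1 and 0 with an estimated correlation. NFKBIA, the inhibitor of NF-kB, rose by 0.97, FOS and SPRY4 by 0.47 and 0.51, SREBF1 by 0.49 and DHCR7 by 0.44, while PMVK fell by 0.47 and NDRG1 by 0.71. Of these calls, that of TXNIP was lost in 2 of 10 fits with 1 array left out, NDRG1 in 3, PMVK in 4, FOS and SREBF1 in 5 each, SPRY4 in 6, AKR1B10 in 8 and DHCR7 in 9. Interferon-stimulated genes stood at a median of -0.675 at 8 h and 0.491 at 50 h against untreated in p53i cells, and at -0.275 and -0.000151 in LacZi cells. Their 50 minus 8 h median over both siRNAs was 0.718 (camera adjusted p = 8.94e-12, and adjusted p = 0.118 with an estimated correlation), with 0 members called over all genes and 15 of 31 higher adjusted over the list alone. Chosen after their values were seen, STEAP4 (1.30), KRTAP3-1 (2.81) and SLC6A14 (2.17) were among the genes higher at 50 than at 8 h.

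Of 31 interferon-stimulated genes 21 were higher in p53i cells, and the list's adjusted p was 0.0859 with an estimated correlation. RNA quality of those arrays is argued against as the whole cause by a list median of 0.957 with the ACTB ratio as a covariate and 1.09 without the arrays with the highest ratio, against 0.998. Of 100 splits into 5 and 5, 10 gave a median as far from 0 (highest other 1.55), so chance was not excluded there. In all 10, however, every D3 pair that was parted was parted along the siRNA. These splits thus carry the siRNA difference itself, and their number cannot decide on chance. Among 24 splits that part each D3 pair, only 1, the real one, gave a median as far from 0 (highest other 0.799). A response to the p53 siRNA molecules may explain the rise as well as loss of mutant p53, and the 2 cannot be told apart: the untreated median of 0.943 is allowed by both, and no other p53 siRNA or rescue array is in the design. Loss of mutant p53 stays open as a hypothesis.

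Of 36 G2/M genes 15 were lower after D3 over the 3 times and 27 at 50 h, and the list's adjusted p with an estimated correlation was 0.158 and 0.13. RNA quality is argued against by a G2/M median of -0.576 at 50 h with the ACTB covariate, against -0.609. A D3 response that needs mutant p53 would give a smaller fall in p53i cells. At 50 h the median was -0.694 there and -0.576 in LacZi cells, each from 1 array at 50 h, so the fall was not smaller. This cannot decide the question, as the knockdown was not measured. Longer time in culture may account for the fall as well as D3. The 2 cannot be told apart, since no untreated array is labelled as harvested with the 50 h arrays and the 8 h median of -0.134 is allowed by both. Of 100 regroupings of the D3 times, 9 gave a median as far from 0 in either direction (size 0.379 against a highest other of 0.453), so chance was not excluded for this list.

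Other counts of regroupings were as follows. For the 529 genes called after D3, 1 of 100 regroupings, the real one, gave as many (highest other 473). The regrouping with 473 left only 2 of the D3 arrays labelled as D3. Its reference group was thus made up of D3 arrays, nearly the reverse of the real one. For the median of the vitamin D receptor targets 1 of 100 gave a value as far from 0 (0.416, highest other 0.334). No other regrouping tried matched either value, but chance differences between cultures are not excluded. For the number of lists called, 26 of 100 splits gave as many as the 5 between siRNAs (highest other 7) and 25 of 100 as many as the 6 after D3 (highest other 11), so chance was not excluded for these counts. The regrouping with 11 lists was the same as that with 473 genes, nearly the reverse of the real one.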
